A study of Gallus gallus with 6 samples.

How the data were processed

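Chicken (Gallus gallus, Leghorn White) embryos were injected on both sides, with the TGFB1 morpholino on one and a control morpholino on the other, and grown to stage 9, per the labels' protocols. RNA of each dorsal neural fold was poly(A) selected and made into strand-specific libraries with NEBNext kits. The deposited table holds whole-number read counts per gene for 24356 Ensembl gene IDs, with exon positions, strands and merged exon lengths. cutadapt, HISAT2, featureCounts and the genome build galGal6 are named in the submitters' processing notes, and their versions, the annotation release and the strand setting of the counting are not given in the sources used here. Because the strand setting is not given, levels of genes that overlap another gene are uncertain, as are those of near-identical copies, whose reads the counting may split. Coordinates are those of the deposited table, counted from 1.

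Groups were taken from the genotype label and pair numbers 1 to 3 from the titles. The numbers pair the samples: the protocol takes both sides of the same embryo, and libraries with the same number deviated together from their group means (correlations over tested genes of 0.49, 0.52 and 0.36 in pairs 1, 2 and 3, and 0.26, 0.46 and 0.29 without the Z, W and mitochondrial genes). W-linked genes also put the libraries of pair 1 together, with 24.0 and 18.3 CPM against 2346 to 2756 CPM in the other 4. They do not tell pair 2 from pair 3. Replicates differed by far more than sampling noise (chi-square per degree of freedom of 12.0 to 64.0), so none was a repeat of another. With 3 pairs, the p-values set the side differences against their spread between 3 embryos. The edgeR test used below estimates that spread partly from the other genes, which weigh in with a mean of 11.0 prior degrees of freedom.

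Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr (12736) were scaled by TMM, whose factors lay between 0.973 and 1.01, and tested with the quasi-likelihood F test in a model with the pair number as a block. P-values were adjusted by Benjamini and Hochberg, with a false discovery rate of 0.05. The block was part of the design before the data were examined, as were all alternatives except those named as added in the closing section. Standard errors were taken as the log2 fold change divided by the root of F. CPM values of single genes use the TMM-scaled library sizes, and log2 CPM within pairs a prior count of 2, while the W-linked CPM and the shares of counts use the unscaled totals. Total counts ran from 5350165 to 12256492 per library. On counts simulated for this comparison 12577 genes were tested, and known changes were given only to genes with a mean of at least 5 CPM. Of 50 genes changed 1.5-fold 46% were recovered, with 94% of those changed 2-fold, 98% at 3-fold and 100% at 4-fold. In that simulation 13 unchanged genes were called and no class was called when none was shifted. The class of chromosomes 30 to 33 was called in a separate simulation that lowered all its genes alike, by more than their observed median. Smaller or uneven shifts of a class were not simulated. Counts were drawn independently for each gene, so the class test was not checked under correlation between genes. The search for runs found 5 of 5 runs that were written into the calls themselves, which checks the code and not the power.

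Gene symbols were to come from a RefSeq table of the assembly GRCg7b, but 0 of the 24356 Ensembl IDs matched it and the files do not pair IDs with symbols. TGFB1 itself and the 27 gene lists fixed before the data were examined were therefore not analysed here. For the same reason the rule for named genes was cut back. It took, among genes past the false discovery rate with a mean of at least 5 CPM and the same direction in all 3 pairs (710 higher, 1009 lower), those with the largest fold changes and the smallest p. From these the 1 ID with the largest fold change and the 1 with the smallest p of the rest are printed per direction.

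In place of the lists, 16 classes of genes were tested with camera (limma 3.58.1, two-sided, preset correlation of 0.01) on voom values in the same design, and adjusted over the 16. They are chromosomes 1 to 5, 6 to 10, 11 to 28, 30 to 33, Z and W, unplaced scaffolds, mitochondrial protein-length features, single-exon genes, the 1274 genes at each end of span and of exon length, the 1274 with the most exons, and genes overlapping another on the same or on the opposite strand. The classes and the runs of at least 4 neighbouring genes were chosen after the data were seen. Mitochondrial features were sorted by length within 3 bases of the RefSeq mitochondrial genes, without giving them names. Regions wider than a run join windows of 8 tested genes with at least 6 called in 1 direction.

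Alternatives were size factors as in DESeq2, the DESeq2 1.42.0 Wald test, limma-voom, no filter, at least 1 CPM in all 6 libraries, no replicate block, the block with a correction for exon length (loess, span 0.5), a false discovery rate of 0.1, and leaving out each pair. The DESeq2 test took all genes with a count in place of the filtered set. Planned corrections for GC content and the removal of haemoglobin genes were not run. The first lacked a genome sequence and the second lacked symbols.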

Results

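Poly(A) RNA was sequenced from single dorsal neural folds of chicken embryos at Hamburger-Hamilton stage 9, around which cranial neural crest cells begin to leave the neural tube. Each embryo carried a morpholino against TGFB1 on one side and a control morpholino on the other, both at 1 mM, and the folds of both sides were taken separately. A morpholino is an antisense oligonucleotide that blocks translation or splicing of its target, and TGFB1 is a secreted ligand of the transforming growth factor beta family, which signals through SMAD2 and SMAD3. The 6 libraries form 3 pairs of sides, with 3 libraries per group. The control libraries of pairs 1, 2 and 3 held 12256492, 8484444 and 5350165 counted reads. The TGFB1 morpholino libraries held 9061190, 9659114 and 7870067. Between 15593 and 16881 of the 24356 annotated genes had a count in each library.

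The comparison of the sides asks which transcripts of the neural folds differ between the TGFB1 and the control morpholino side. The knockdown itself was not checked here, and differences between left and right were not tested. On the TGFB1 morpholino side 911 genes were higher and 1122 genes were lower, out of 12736 tested, at a false discovery rate of 0.05. The median log2 fold change was 0.84 among the genes that rose and -0.80 among those that fell. More than 2-fold changes were found for 359 of the genes that rose and 379 of those that fell. Of the 911 genes that rose 903 were higher in all 3 pairs, and of the 1122 that fell 1121 were lower in all 3, which follows largely from calling them by a paired test. The median log2 fold change over all tested genes was 0.0032. The sides also parted on the first principal component, which held 38.5% of the variance and placed the controls between -36.4 and -21.3 and the TGFB1 morpholino libraries between 16.3 and 41.6. The second component, with 31.1%, set pair 1 apart from pairs 2 and 3, from which it also differed in W-linked and Z-linked counts. Z-linked genes took 3.70% and 3.61% of the counts in pair 1 and 2.41% to 2.52% in pairs 2 and 3.

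These counts rest on comparing sides within a pair, since a fit with no replicate block called 270 genes higher and 427 lower, all of them among those above. Without pair 2 the counts were 450 and 670, and the DESeq2 Wald test, run with no filter, called 514 genes higher.

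The gene with the largest fold increase among those with at least 5 CPM (read counts scaled to library size) was ENSGALG00000016651.7, which has 9 exons on the plus strand of chromosome 3, from 107177930 to 107186837 in galGal6. It rose from 11.6 ± 2.23 CPM on the control side to 81.2 ± 5.21 CPM on the TGFB1 morpholino side (SD, n = 3), a 7.02-fold change (log2 2.81, SE 0.16, adjusted p = 7.03e-07). It also had the smallest p among the genes that rose. The next smallest at this level belonged to ENSGALG00000005572.6, with 8 exons on the minus strand of chromosome 14, from 6553214 to 6557431. Its level went from 31.4 ± 9.32 to 116.2 ± 19.8 CPM (SD, n = 3), a log2 fold change of 1.91 (SE 0.14, adjusted p = 5.37e-06). It overlaps a gene on the opposite strand, so its level is uncertain.

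Among the genes that fell, ENSGALG00000004386.6 had the smallest p. It has 3 exons on the plus strand of chromosome 18, from 8785940 to 8789042, and went from 79.7 ± 40.7 CPM in the controls to 12.9 ± 6.66 CPM on the TGFB1 morpholino side (SD, n = 3). Its log2 fold change was -2.62 (SE 0.15, adjusted p = 7.03e-07). The SDs cover a spread between embryos that both sides share, for the control level was 33.5 CPM in pair 2 and 110.3 CPM in pair 3, and the TGFB1 morpholino level was 5.48 and 18.3 CPM in the same pairs. Among genes with a mean of at least 5 CPM that fell in all 3 pairs, the largest fold decrease belonged to ENSGALG00000029811.2, with 15 exons on the minus strand of chromosome 2, from 47461980 to 47608491. It went from 9.91 ± 10.1 to 1.15 ± 1.19 CPM (SD, n = 3), a log2 fold change of -3.10 (SE 0.34, adjusted p = 1.03e-04). It too overlaps a gene on the opposite strand, and with no replicate block its adjusted p was 0.0668, at the upper end of a range from 7.50e-16 over its alternatives.

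**Figure D1:**
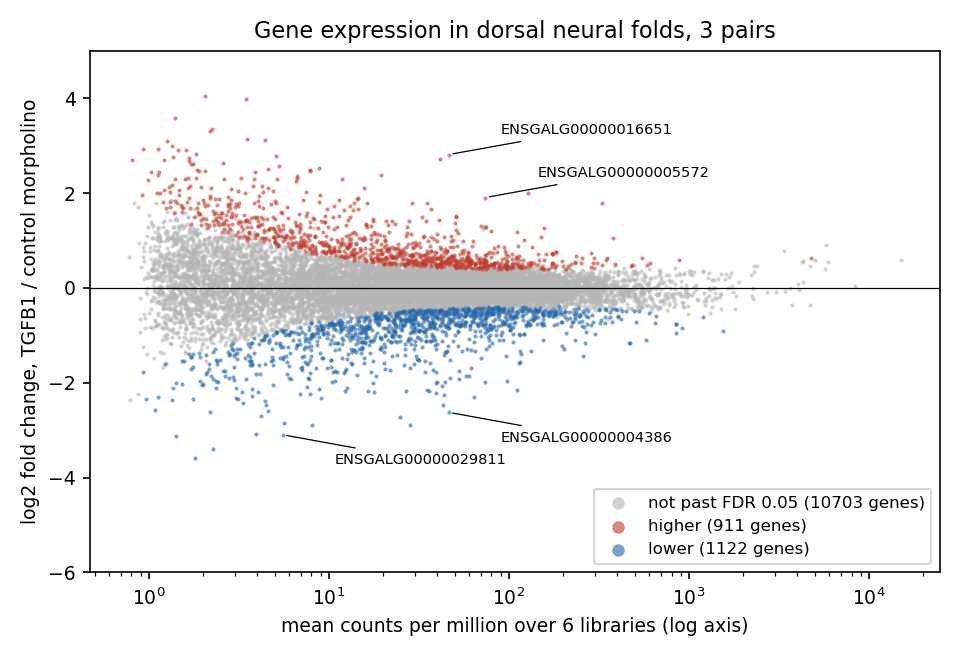
Log2 fold change of the 12736 tested genes (TGFB1 over control morpholino side, vertical axis) against their mean level in CPM over the 6 libraries (horizontal log axis), with genes past a false discovery rate of 0.05 in red (911 higher) and blue (1122 lower). The 4 gene IDs described in the text are marked.

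The share of genes that fell differed between chromosomes and was highest on chromosomes 16 and 30 to 33 and on scaffolds without a chromosome. On chromosomes 30 to 33, 118 of 431 tested genes fell (27.4%) and 29 rose (6.73%), and the class median log2 fold change was -0.051, -0.26 and -0.26 in pairs 1, 2 and 3. On chromosomes 1 to 5, by comparison, 415 of 5326 fell (7.79%) and 359 rose (6.74%). Of the 81 genes on unplaced scaffolds, 33 fell (40.7%) and 5 rose, with a median log2 fold change of -0.55 over the class and medians of -0.43, -0.61 and -0.56 in pairs 1, 2 and 3. With no filter on low counts 40 of 190 such genes fell and 10 rose, with a median of -0.23. Chromosome 16, the microchromosome that carries the chicken major histocompatibility complex, had 12 of 44 genes lower. Chromosomes 25 and 31 had high shares in both directions, with 36 of 189 genes lower and 26 higher on chromosome 25, and 14 of 43 lower and 6 higher on chromosome 31. The median log2 fold change was 0.0057 on chromosome 31, against -0.28 on chromosome 30, -0.27 on 32 and -0.094 on 33, so the genes of these 4 chromosomes were not lower throughout. On the sex chromosomes 26 of 550 Z-linked genes fell and 32 rose, and 2 of 30 W-linked genes rose. The W-linked result rests on pairs 2 and 3, as the control and TGFB1 morpholino libraries of pair 1 held 294 and 166 W-linked counts.

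**Figure D2:**
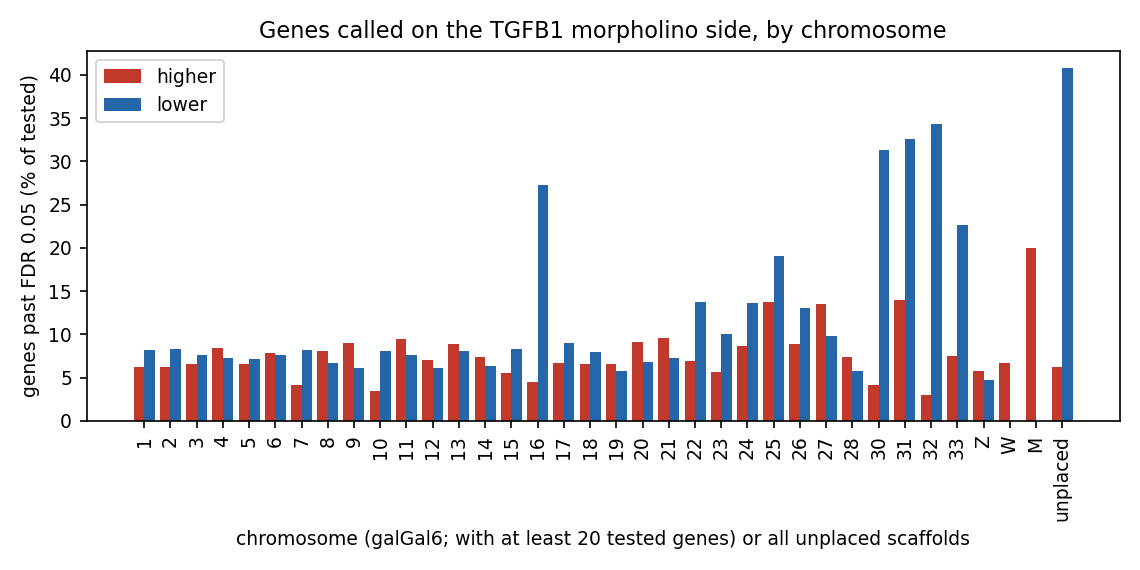
Percentage of tested genes past a false discovery rate of 0.05 (vertical axis) that were higher (red) or lower (blue) on the TGFB1 morpholino side, for each chromosome with at least 20 tested genes and for all unplaced scaffolds together. The blue bars reach 31.2% on chromosome 30, 32.6% on 31, 34.3% on 32, 22.7% on 33 and 40.7% on unplaced scaffolds.

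Of 16 classes of genes set by position and structure, camera with its preset correlation called 5. Genes of chromosomes 30 to 33 (median log2 fold change -0.16, adjusted p = 1.65e-04) and of unplaced scaffolds (adjusted p = 2.88e-07) were lower as classes than the other genes. So were the 1274 genes of widest span (median -0.14, adjusted p = 0.00264) and the 1274 with the longest exon sequence (median -0.11, adjusted p = 0.0108). Mitochondrial features of protein-coding length were higher (median 0.54, adjusted p = 8.03e-06). None of the 5 calls held in camera with an estimated correlation. Unplaced scaffolds then had an adjusted p = 0.603 and the other 4 classes an adjusted p = 0.756. That setting also tests on the few residual degrees of freedom of 3 pairs, so a loss there cannot be laid to correlation alone. The estimated correlation was 0.016 for unplaced scaffolds and 0.043 to 0.38 for the other 4 classes. Another split of the 6 libraries called 7 classes with the preset correlation. The median of chromosomes 30 to 33 was -0.25 without pair 1 and -0.099 with no filter on low counts. Without pair 3 the calls for wide span (median -0.12, adjusted p = 0.0556) and for long exon sequence (-0.055, adjusted p = 0.681) were lost. They were also lost with a correction of each library for exon length, where the medians were -0.084 (adjusted p = 0.0834) and 0.0071 (adjusted p = 0.978). That correction takes out any trend with exon length, so the loss for long exon sequence follows from its construction. With no replicate block fewer genes fell: 69 on chromosomes 30 to 33, 21 on unplaced scaffolds and 66 of the widest span.

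The 1274 genes of widest span, with a median of 124.4 kb from the first to the last base, included 166 that fell and 49 that rose. The 1274 narrowest, with a median of 1.79 kb, included 110 that fell and 100 that rose. The median log2 fold change went from 0.11 in the narrowest to -0.14 in the widest, a difference of 0.25 that was 0.14 after the exon length correction. Across genes, which are not independent replicates, Spearman's correlation of span with the fold change was -0.18, and it was -0.17, -0.055 and -0.17 in pairs 1, 2 and 3. The slope of log2 CPM on log2 span differed between the sides by -0.056, -0.0090 and -0.040 in pairs 1, 2 and 3, and by up to 0.061 between embryos of 1 group.

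Some of the called genes lay next to others called in the same direction. There were 19 runs of at least 4 consecutive tested genes called in 1 direction, 14 of them lower and 5 higher, with 85 of the 2033 called genes in all. When the calls were shuffled among the genes of each chromosome 10000 times, runs of lower genes averaged 2.99 (at most 11) and runs of higher genes 0.37 (at most 4). Both one-sided permutation p-values were 1e-04, the smallest that these shuffles can give. Shuffling treats genes as independent, so these p-values concern how the calls cluster along chromosomes and not the spread between embryos. The minimum of 4 genes was chosen after the data were seen. The number of runs was 3 with no replicate block, 5 with DESeq2, 12 with no filter on low counts and 10 without pair 2. DESeq2 was also run with no filter, and the low-count genes then tested can part neighbours called in 1 direction.

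The longest runs held 6 genes that fell and lay on chromosome 25, from 674810 to 1323218 and from 1436842 to 1527326, with median log2 fold changes of -1.51 and -1.25. Between 482603 and 1550485 of that chromosome, 12 of the 18 tested genes fell and 1 rose. Runs of 5 genes that fell were found on chromosome 26 from 1792379 to 2003254 (median log2 fold change -0.78), on chromosome 27 from 281766 to 2046860 (-1.67), on chromosome 31 from 2641642 to 2783924 (-1.16) and on chromosome 33 from 3412284 to 3801104 (-1.49). The wider region of chromosome 31 from 2259401 to 4765753, most of it a stretch without tested genes, had 13 of 18 tested genes lower. It was followed at once by 4 genes that rose, from 4766810 to 4866801, by log2 fold changes of 1.35 to 2.79. The single run of 5 genes that rose lay on chromosome 1 from 88956754 to 89260695, all on the minus strand, with log2 fold changes of 1.05 to 2.29.

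**Figure D3:**
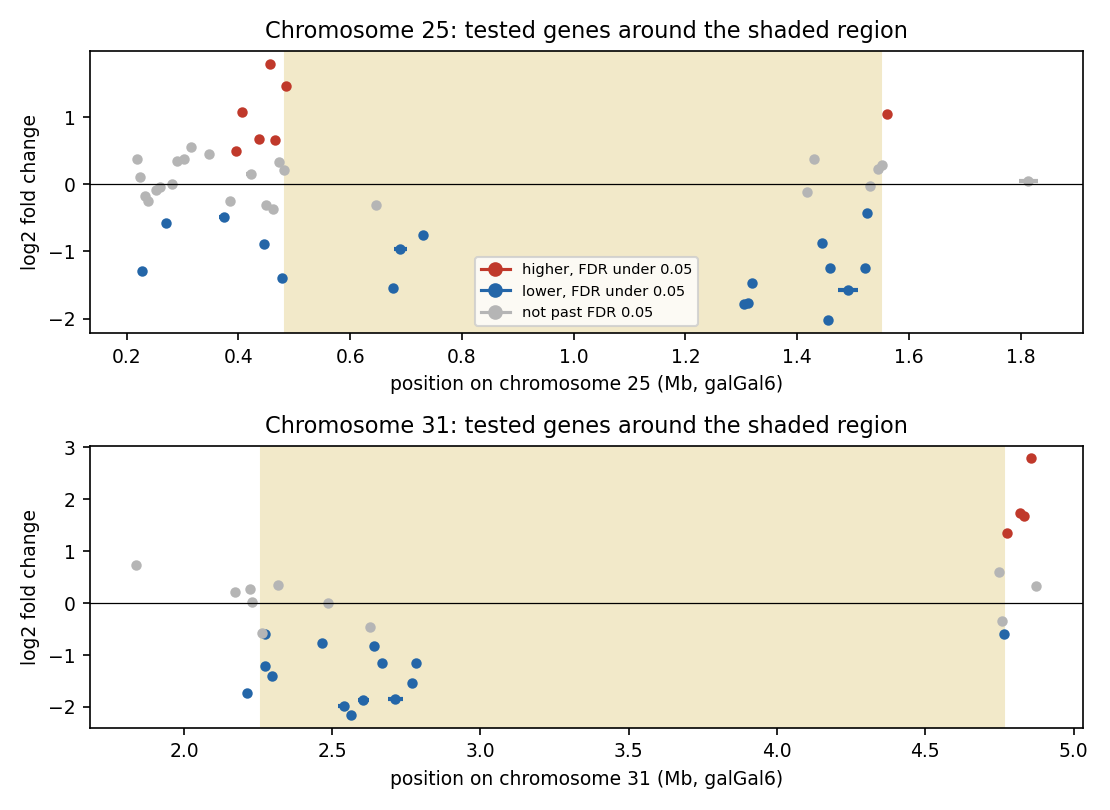
Log2 fold change (TGFB1 over control morpholino side, vertical axis) of tested genes along parts of chromosomes 25 and 31 (horizontal axis, Mb in galGal6), each gene drawn as a bar over its span with a point at its middle, red or blue where past a false discovery rate of 0.05 and grey otherwise. The shaded regions hold 12 of 18 and 13 of 18 genes that were lower, and 4 genes to the right of the shaded region of chromosome 31 were higher.

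Mitochondrial transcripts took 4.63 ± 0.99% of the counts on the control side and 7.99 ± 3.55% on the TGFB1 morpholino side (SD, n = 3), and were higher in 3 of 3 pairs. An exact sign-flip test over the pairs, two-sided, gave p = 0.25, the smallest that 3 pairs allow. Features with the lengths of the 13 mitochondrial protein-coding genes took 4.41 ± 0.96% and 6.36 ± 1.40% (SD, n = 3), again higher in 3 of 3 pairs with an exact p = 0.25. Their log2 fold changes ran from 0.30 to 0.63, 11 of the 13 were higher in all 3 pairs, and 2 passed the false discovery rate over all genes tested by edgeR (11 at an unadjusted p under 0.05). That number varied with the method: DESeq2 on unfiltered genes called 10 of the 13, limma-voom 8, and edgeR with no filter on low counts 8. Without pair 1 edgeR called 11, without pair 3 it called 1 and without pair 2 it called 0 (1 at an unadjusted p under 0.05). With no replicate block it called 0 (5 at an unadjusted p). Fits without a pair have fewer embryos to estimate the spread from and lean more on other genes. More calls there are therefore not a firmer result. In the TGFB1 morpholino library of pair 1, the 2 features with the lengths of the mitochondrial rRNAs took 4.56% of the counts, against 0.148% to 0.255% in the other 5 libraries. These lie on the mitochondrial chromosome from 1297 to 2272 and from 2346 to 3966. They were 19.1 and 26.2-fold higher than in the paired control in pair 1, and 0.68 and 0.65-fold of the control in pair 2 and 0.73 and 0.84-fold in pair 3. Neither passed the test over the 3 pairs (adjusted p = 0.50 and 0.47). Without pair 1, which holds that library, 940 genes were higher and 1313 lower.

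**Figure D4:**
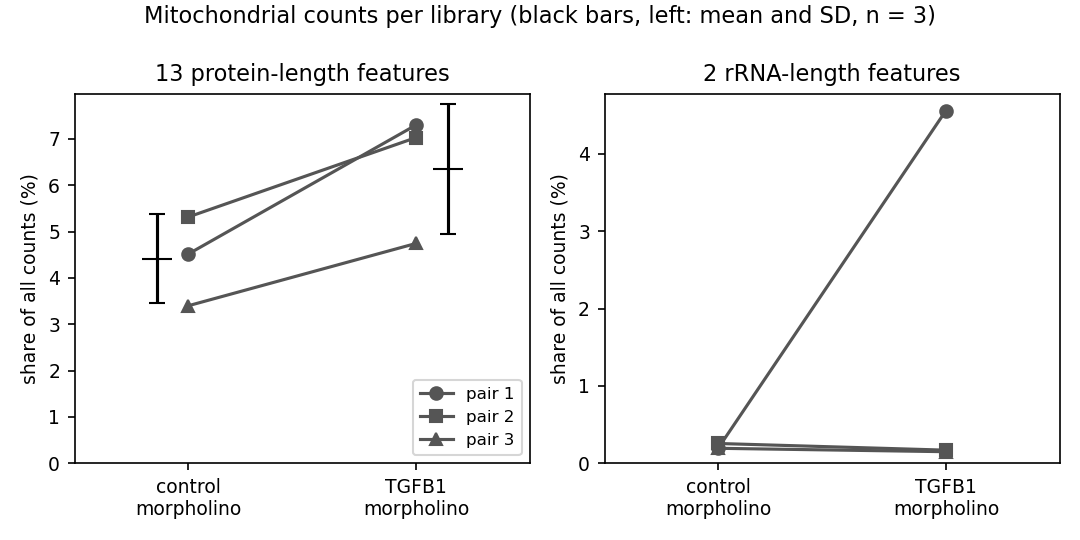
Share of all counts (vertical axes, percent) of the 13 protein-length (left) and the 2 rRNA-length (right) mitochondrial features in each library, with lines joining the sides of a pair and black bars on the left for the mean and SD of 3 libraries. The protein-length share is higher on the TGFB1 morpholino side in 3 of 3 pairs, and the rRNA-length share reaches 4.56% in 1 library.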

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

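The gene span correction, the removal of mitochondrial genes and all alternatives for classes and runs were added after the data were seen. With no replicate block 270 genes were higher and 427 lower, and 3 runs were left. ENSGALG00000029811.2 then no longer passed, and it was not tested at 1 CPM in all 6 libraries, while the other 3 printed IDs passed in every alternative. DESeq2, run with no filter, called 514 genes higher and found 5 runs, and a false discovery rate of 0.1 gave 1420 genes higher. Leaving out each pair in turn gave 450 to 940 genes higher, 670 to 1313 lower, 10 to 16 runs and 3 to 6 classes. The lowest counts of genes and of runs came without pair 2, and those of classes without pair 3. Fits without a pair have fewer embryos to estimate the spread from and lean more on other genes, so their counts measure robustness poorly. The adjusted p by edgeR of ENSGALG00000016651.7 was 3.32e-49, 7.04e-24 and 6.01e-07 without pairs 1, 2 and 3. With all pairs it was 7.03e-07, while the log2 fold change without a pair stayed between 2.69 and 2.93. Of the 911 genes higher, 407 were called again without pair 2, and of the 1122 lower, 632. Under the other alternatives the counts of genes stayed within 1.5 times. Runs numbered 12 with no filter on low counts and 47 when 3 genes sufficed. The classes called numbered 3 with the exon length correction and 3 with the span correction. Camera with an estimated correlation, which also rests on few residual degrees of freedom, called 0 (1 at an unadjusted p under 0.05). Fry, a test of whether a class moves on balance 1 way, called 0 (2 at an unadjusted p). The class of longest exon sequence turned to a median log2 fold change of 0.0071 under the exon length correction, and that of widest span to 0.0073 under the span correction, each by the correction's own construction. The cause of the other changes was not tested. In the simulation 46% of 1.5-fold changes were found at this depth, in genes with a mean of at least 5 CPM. Smaller changes are missed more often, and changes in genes below that level were not simulated.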

Other observations

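Among the tests below, those of equal mitochondrial RNA and of a morpholino response for the rRNA-length features were chosen after the result was seen. Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split called 911 genes higher and 1122 lower by edgeR's quasi-likelihood test with the pair block, and the highest other split 0 in either direction (1 of the 10 splits gave as many). Of the other 9 splits, 3 part all 3 pairs as the real one does, and 6 part 1 pair, so that with the block they rest on 1 library against 1 and give only 3 distinct fits. The other 3 keep the difference between the real sides in their residual spread, so a low count is expected from all 9. By unadjusted p under 0.05 the real split gave 3941 genes, the 3 that part all pairs at most 116 and the 6 that part 1 pair at most 1199. Limma-voom called 2155 genes in the real split, 0 in those 3 and at most 2 in those 6. The real split gave 19 runs and the highest other 0 (again 1 of 10), which adds nothing, as no run can form without called genes. Of the classes the real split called 5, the other 3 that part all pairs called 2, 7 and 6, and 5 of the 10 splits called at least 5.

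Genes of unplaced scaffolds were lower on the TGFB1 morpholino side, with differences in mean log2 CPM of -0.39, -0.56 and -0.70 in pairs 1, 2 and 3. Gene span and exon length are argued against as the whole cause. Placed genes matched on span and level had a median log2 fold change of 0.079, as had those matched on exon length and level. This lies above the 95% bootstrap interval of the unplaced median (-0.89 to -0.29). The interval resamples genes, which are not independent replicates, and leaves out the spread between embryos, so it may be too narrow. Exon number and GC content were not matched and stay untested. A trend between libraries that has nothing to do with the morpholino cannot be told apart. The class mean differed within a group by up to 0.43, which is 0.779 of the mean difference of 0.55 between the sides, but that spread lies between embryos, whereas the differences within the 3 pairs were of 1 sign, as 3 pairs can be by chance. Reads shared between near-identical copies, and a response to the knockdown, stay open and were not tested.

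Runs of neighbouring genes called in 1 direction may arise where gene models overlap and are counted for the same reads. After the 2131 tested genes that overlap another were left out, 13 runs were found among 10605 genes. In 2000 shuffles within chromosomes the mean was 2.84 and the 95% range 0 to 6. Overlapping models therefore do not account for all of the runs. Neighbouring copies of a gene family that share reads, and regulation shared by neighbours as a response to the knockdown, are candidate explanations that remain open and were not tested.

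The mitochondrial rRNA-length features stood out in the TGFB1 morpholino library of pair 1 alone. Both features were lower on the TGFB1 morpholino side in 2 pairs, so no rise was shared by all 3 pairs. The pattern was picked for standing out in 1 library, so this restates it and cannot decide on a response to the morpholino. A response in that embryo alone cannot be told apart. More mitochondrial RNA of every kind in that library is argued against. In pair 1 the lower of the 2 log2 differences exceeded the median of the protein-length features by 3.67. Those features had an SD of 0.29 in pair 1. Incomplete poly(A) selection in that library cannot be told apart from other causes. Nuclear features of at most 200 bases had a median log2 difference of 0.487 in pair 1, against -0.12 and 0 in pairs 2 and 3. The 95% bootstrap interval in pair 1, over features and not over embryos, was 0.34 to 0.62. The median in pair 1 lies below the 1 set for it in advance and not clearly below 0.5. The 15 mitochondrial features of tRNA length had medians of 1.32, 0.33 and 0.19 in the 3 pairs.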
